A study of Mus musculus with 5 samples.

How the data were processed

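The series holds 5 Affymetrix arrays of mouse thymic cell suspensions, and each array measured RNA from a pool of 3 male CD-1 mice, an outbred stock, aged 4 to 6 weeks. The groups, taken from the sample descriptions, were untreated animals, animals 4 h after an intraperitoneal injection of phosphate-buffered saline (PBS), animals 4 h after an injection of 0.2 mg dexamethasone, suspensions cultured for 4 h with 0.1% ethanol, and suspensions cultured for 4 h with dexamethasone at a concentration the labels write as 10e-7 M. Each group had 1 array, so no difference between a pair of arrays has a replicate check. The number of arrays limits the precision of every value.

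The deposited series matrix held a linear intensity for each of 45101 probe sets on each array, which the authors obtained with RMA per the submitters' processing notes. The version and settings of RMA are not given in the sources used here. The deposited table of expression values held the same measurements as log2 values, and the largest absolute difference from the log2 of the matrix was 7.11e-15. A further deposited table gave log2 differences between the dexamethasone arrays and their vehicle arrays, which equalled differences of those log2 values to within 1.78e-15. The authors' deposited table for the in vivo comparison listed 1260 probe sets, which were exactly the 1260 with an absolute log2 difference of at least 1. The median deposited log2 value per array lay between 4.23 for cultured dexamethasone and 4.37 for untreated. Between 41.1% and 42.6% of the probe sets on an array shared their value, compared at 5 decimals, with another probe set of the same array. Among kept genes, 260 had a difference of exactly 0 in vivo and 294 in vitro. The files used here gave no detection calls and no scan dates.

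Gene symbols came from the deposited tables and were updated through a RefSeq gene table of assembly GRCm38.p6, which was used for names and for which genes neighbour each other. Of the probe sets, 22692 carried a current symbol, 1563 were named by accession, 11309 by a unique synonym and 4759 kept the symbol of the file. A further 4714 were unnamed and 64 were control probe sets. Each of 19764 symbols was represented by its probe set with the highest mean log2 value over the 5 arrays. The 9882 genes whose mean was at or above the median over genes, 5.28, were kept, and 6489 of them had more than 1 probe set. Another probe set of the gene differed by at least 2-fold in the opposite direction for 1 of the genes counted in vivo, 1 in vitro, 1 between PBS and untreated and 8 between ethanol culture and untreated. Probe sets of a gene also differed in size: the 5 of Nr3c1 ran from -0.28 to 1.71 in vivo, the 4 of Fkbp5 from 0.07 to 2.88, and the 2 of BC018473 from 0.24 to 6.38.

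Values were compared as differences of log2 levels, and genes differing by at least 1 were counted in each direction. The comparisons were dexamethasone minus PBS in vivo, dexamethasone minus ethanol in vitro, PBS minus untreated and ethanol culture minus untreated. The dexamethasone comparisons shared no array. The overlap of their lists was set beside the overlap of independent lists. The difference common to both settings was tested with limma 3.58.1 in R 4.3.3, as an additive model of setting and dexamethasone over 4 arrays with eBayes and a mean-variance trend. Benjamini-Hochberg adjustment ran over the kept genes, with a threshold of 0.05. The model left 1 residual degree of freedom per gene, which is the difference between the responses in the 2 settings, so its p-values do not measure the spread between pools of 1 group. A total of 17 genes had a residual of exactly 0, and 0 of these were called. Words of change are used only for genes that passed this test.

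The 27 gene lists, among them markers of 10 cell types, were fixed before the data were examined. They covered canonical glucocorticoid-induced genes, the glucocorticoid receptor and chaperones, pro-apoptotic and anti-apoptotic Bcl-2 family genes, caspases and apoptosome, p53 targets, double-positive thymocyte genes, T cell receptor and CD3 complex signalling, mature single-positive thymocyte genes, T cell receptor activation response, immediate-early and heat shock genes, NF-kB and cytokine genes, interferon response, glycolysis, cholesterol synthesis, amino acid and endoplasmic reticulum stress response, ribosome biogenesis, DNA replication, mitosis, and markers of macrophages, dendritic cells, thymic epithelium, B cells, stromal fibroblasts, endothelium, erythroid cells and granulocytes. Each list's median difference was placed among 10000 random lists of the same size matched on mean level in 10 bins, as a description of these arrays. A median outside the central 95% is called above or below random lists. Median and mean had opposite signs for interferon response and NF-kB and cytokine genes in vitro, thymic epithelium in vivo, glycolysis and macrophage markers between PBS and untreated, and caspases between ethanol culture and untreated.

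Genes were named by a rule fixed before the data were examined. It took the 10 highest and 10 lowest genes in each dexamethasone comparison and for both settings together, the 5 lowest p-values in each direction of the limma test, and the 8 highest and 8 lowest genes in each control comparison. It also took the 6 highest and 6 lowest differences between the responses in the 2 settings, up to 4 members of each list with the largest difference, the 2 members of each cell type list with the highest level, and the receptor gene Nr3c1. Members of a list that passed the limma test are also named with their count, and a few other genes are named in the closing section with the remark that they were chosen after their values were seen. A few genes that this rule selects are not reported here and are left out of the counts of alternatives per named gene.

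The procedures were tested on simulated data. In simulated values for the common dexamethasone difference over 9882 genes with 200 changed, the limma fit recovered 64.0% of changes of 1 and 97.0% of changes of 2 on the log2 scale. It called 172 genes, of which 11 were false. Every simulated change was of the same size in both settings, so these rates do not cover genes that respond in only 1 setting. Of 1000 random lists of 15 genes, 6.1% lay outside the central 95%, and of 100 lists shifted by 0.5 on the log2 scale 98.0% did. For the count of neighbouring genes, sets of 50 genes exceeded the upper limit of the central 95% of random sets in 0.5% of 200 draws without planted neighbours, in 13.0% with 6 planted neighbours and in 76.5% with 12. A first form of this simulation used a single draw per setting and did not separate 6 planted neighbours from random sets, so it was replaced, after that failure, by these rates over 200 draws. An earlier run of the random lists with fewer draws gave a higher rate outside the central 95%. The neighbour test therefore misses small groups of neighbours often.

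Alternatives covered the level filter, the fold threshold, the choice of probe set, centring and cyclic loess normalization of the 5 arrays, the deposited log2 and difference tables, the untreated array as control, and other forms of the limma fit. The analysis ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Leaving out a replicate and regrouping samples were not possible with 1 array per group.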

Results

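Transcript levels were measured on 5 arrays of thymic cell suspensions, 1 array per group, to compare glucocorticoid-treated samples with their vehicle controls in living animals and in culture. Dexamethasone is a synthetic glucocorticoid, and most cells of the thymus are developing T cells that carry CD4 and CD8 together (double-positive thymocytes). All values are log2 levels or differences of log2 levels between a pair of arrays unless a fold is stated. No difference between a pair of arrays has a replicate check. Across probe sets, Pearson's r was 0.992 between untreated and PBS, 0.985 between PBS and in vivo dexamethasone, 0.990 between both cultured arrays and 0.962 between untreated and ethanol culture.

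In living animals, the dexamethasone pool had higher levels of known glucocorticoid targets and of immediate-early genes than the PBS pool. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, was 6.76-fold higher, Fkbp5, an Hsp90 co-chaperone, 3.72-fold higher, and Dusp1, a MAP kinase phosphatase, 9.36-fold higher. Fos, an AP-1 subunit, was 19.1-fold higher. Lower genes included Ccnd3, which encodes cyclin D3, at -2.04, and Bcl11b, a T-lineage transcription factor, at -1.28. In all, 268 genes were at least 2-fold higher and 146 at least 2-fold lower among 9882 kept genes, while PBS against untreated gave 19 and 37.

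The 10 highest genes in vivo were BC018473 (6.38), Thbs1 (5.12), MGC58382 (4.65), Fos (4.26), Nfil3 (3.98), Ston1 (3.89), Zfp704 (3.64), Atf3 (3.52), Ccn1 (3.50) and Sytl3 (3.50). The BC018473 value rests on a PBS level near the lower quartile of all probe set values, and its other probe set was at 0.24. In ethanol culture, without dexamethasone, BC018473 stood at 11.02. Among the 10 lowest were Tdrd5 (-2.64), H2-T18 (-2.43), Tctex1d1 (-2.42), Ankrd6 (-2.41), C230098O21Rik (-2.36), Ptp4a3 (-2.05), Ccnd3 (-2.04), S1pr3 (-2.04) and Nop16 (-1.86). Of 23 measured canonical glucocorticoid-induced genes, 13 were at least 2-fold higher and 1 at least 2-fold lower, with a median of 1.42. Cebpd (3.28), Errfi1 (3.21) and Mt1, a metallothionein gene that was 8.02-fold higher, had the largest differences of that list beside Dusp1. The 15 immediate-early and heat shock genes had a median of 0.93, and 7 of them were at least 2-fold higher, among them Jun (3.17) and Ier3 (2.09). The 12 pro-apoptotic Bcl-2 family genes had a median of 0.48, the 14 p53 targets 0.43, the 13 genes of the T cell receptor activation response 0.24, the 14 macrophage markers 0.43 and the 10 stromal fibroblast markers 0.20, all above random lists. The activation list was split, with 8 genes higher and 5 lower and a mean of 0.08. Some lists share members, such as Bbc3 in the pro-apoptotic and p53 lists, so they are not separate evidence. Among macrophage markers, Hmox1, a heme-degrading enzyme, was higher by 2.37 and Mrc1, the mannose receptor, by 1.68, while the abundant Lyz2 differed by -0.06.

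Lists below random lists in vivo were cholesterol synthesis (-0.73, 19 genes), ribosome biogenesis (-0.53, 17 genes), double-positive thymocyte genes (-0.51, 18 genes), erythroid markers (-0.50, 4 genes), DNA replication (-0.45, 22 genes), NF-kB and cytokine genes (-0.43, 13 genes), interferon response (-0.42, 15 genes), granulocyte markers (-0.37, 7 genes) and T cell receptor and CD3 complex signalling (-0.27, 18 genes). Of the double-positive list, 17 of 18 genes were lower, with Ptcra, the pre-T cell receptor chain, at -1.36 and Endou at -1.25. Cdc6 (-1.13) and Mcm2 (-0.97), which license replication origins, led the DNA replication list, and Myc (-1.17) and Nop58 (-0.95) were lower among ribosome biogenesis genes. Within the range of random lists lay the medians of glucocorticoid receptor and chaperones (0.04), anti-apoptotic Bcl-2 family (0.21), caspases and apoptosome (-0.19), mature single-positive thymocyte genes (0.11), glycolysis (-0.17), amino acid and endoplasmic reticulum stress response (0.10), mitosis (0.03), dendritic cell (-0.07), thymic epithelium (0.12), B cell (-0.10) and endothelial markers (-0.24). Perp was at 0.83, Pfkfb3 at 0.88, Psmb11 at -1.46 and Blk at -0.86. Without the level filter 449 genes were higher and 195 lower.

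In culture, dexamethasone went with higher levels of some of the canonical receptor targets, while the immediate-early genes Fos and Atf3 differed little. Fkbp5 was 4.30-fold and Tsc22d3 5.02-fold higher than with ethanol, and Nfil3, a basic leucine zipper repressor, was 16.8-fold higher. Fos was 1.19-fold higher and Atf3 differed by -0.24. Id3, which encodes an inhibitor of E proteins, was at -1.93. In all, 151 genes were at least 2-fold higher and 85 at least 2-fold lower.

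The 10 highest genes in vitro were MGC58382 (4.44), Dleu7 (4.11), Nfil3 (4.07), Usp18 (3.87), Dipk1b (3.83), Gpr65 (3.78), Fzd5 (3.77), Nars2 (3.55), Cers4 (3.25) and Plagl1 (3.07). Among the 10 lowest were Socs3 (-1.99), Tubb2a-ps2 (-1.94), Id3 (-1.93), Scn4b (-1.91), Clec7a (-1.73), Pik3r3 (-1.62), Cd83 (-1.62) and Agfg2 (-1.61). Above random lists were canonical glucocorticoid-induced genes (0.53, with 8 of 23 at least 2-fold higher), stromal fibroblast markers (0.31), DNA replication (0.24), granulocyte markers (0.24), thymic epithelium markers (0.21) and ribosome biogenesis (0.20). Below them were cholesterol synthesis (-0.74, with 18 of 19 genes lower), dendritic cell markers (-0.37), double-positive thymocyte genes (-0.32), anti-apoptotic Bcl-2 family (-0.29), interferon response (-0.17) and mature single-positive thymocyte genes (-0.12). Hmgcs1 (-1.35) and Msmo1 (-1.27), which encode enzymes of sterol synthesis, were lower than with ethanol, but at 0.27 and 0.06 against the untreated array. The cholesterol synthesis list had median levels of 6.91 untreated, 7.63 in ethanol culture and 6.91 in cultured dexamethasone. Among dendritic cell markers the MHC class II genes H2-Ab1 (-1.15) and H2-Aa (-0.84) were lower. Pdgfrb (2.87) and Col1a1 (1.33), of the fibroblast list, were higher in the cultured dexamethasone array, from ethanol levels of 3.89 and 3.70. The fibroblast list had median levels of 3.80 and 4.15 on the cultured arrays, under those arrays' medians of 4.26 and 4.23. The thymic epithelium list had 4.35 and 4.57, close to those medians, against 9.34 untreated. Random lists were matched on the mean over all 5 arrays, not on these low levels in culture.

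Within the range of random lists in vitro lay glucocorticoid receptor and chaperones (0.15), pro-apoptotic Bcl-2 family (0.19), caspases and apoptosome (-0.04), p53 targets (0.05), T cell receptor and CD3 complex signalling (-0.01), T cell receptor activation response (0.18), immediate-early and heat shock genes (0.03), NF-kB and cytokine genes (0.02), glycolysis (0.06), amino acid and endoplasmic reticulum stress response (0.10), mitosis (0.08), macrophage (-0.10), B cell (-0.26), endothelial (-0.18) and erythroid markers (-0.22). The interferon list's mean was 0.08, opposite in sign to its median, with Usp18 at 3.87 and Ifit1 at -1.19. Against the untreated array in place of ethanol, 496 genes were higher and 844 lower.

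**Figure D1:**
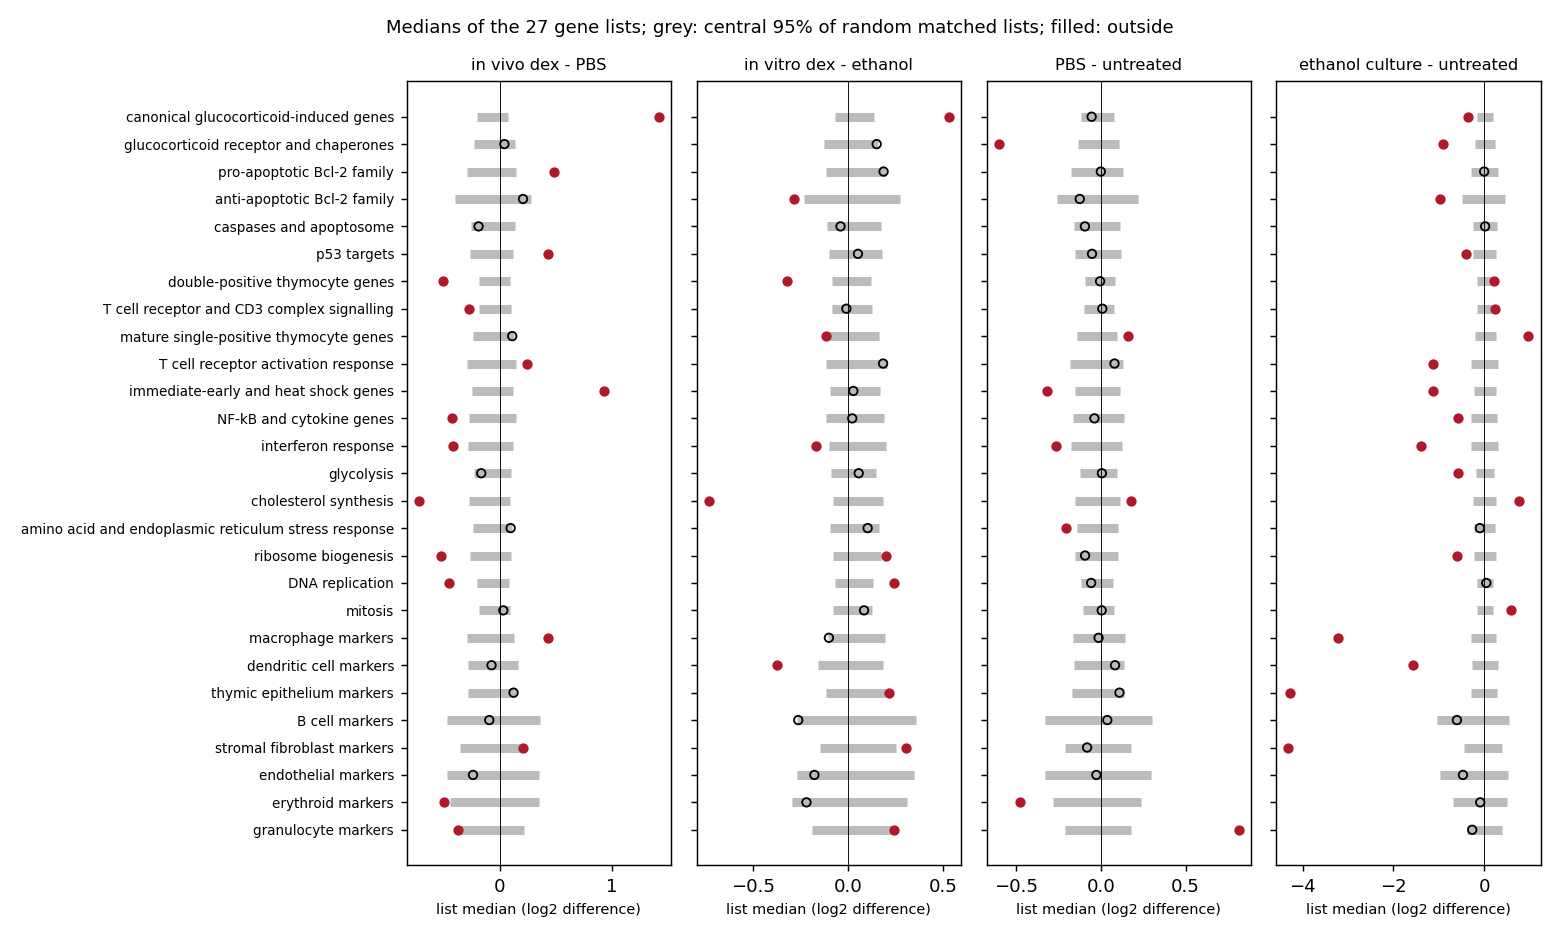
Each row is 1 of the 27 gene lists and each panel 1 comparison, with the list's median log2 difference on a horizontal axis whose range differs between panels. Grey bars span the central 95% of 10000 random matched lists and filled points lie outside it. Canonical glucocorticoid-induced genes stood at 1.42 in vivo and 0.53 in vitro, and cholesterol synthesis at -0.73 and -0.74.

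Genes that differed in both settings included the glucocorticoid targets Fkbp5 and Tsc22d3, the pro-apoptotic genes Bbc3, Bmf and Bcl2l11 and, on the lower side, Bcl11b. In all, 93 were at least 2-fold higher in both settings, where independent lists would share 4.10, and 24 were at least 2-fold lower, where 1.26 would be shared. The 10 highest by the smaller of both differences were MGC58382, Nfil3, Dipk1b, Ston1, Sytl3, Ptgr1, Cers4, Zfp704, Gpr65 and Acer2, which encodes an alkaline ceramidase. Among the 10 lowest were Id3, Tdrd5, Ankrd6, D16Ertd727e, Cxcr6, Hivep3, Agfg2 and Snn. Across the 9882 genes, which are not independent replicates, Pearson's r between the 2 responses was 0.444 and Spearman's rho 0.282. Of 414 genes at least 2-fold different in vivo, 331 had the same sign in vitro, against 5236 of all 9882.

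**Figure D2:**
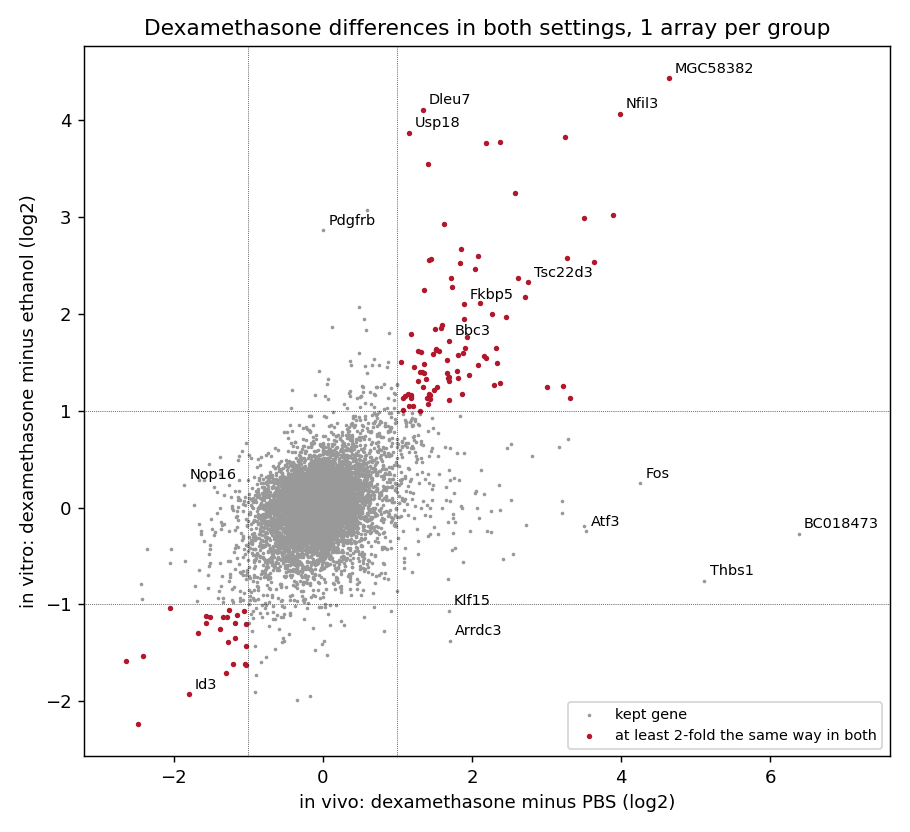
Each point is 1 kept gene, with its in vivo difference (log2) on the horizontal axis and its in vitro difference (log2) on the vertical axis. Red points are the 93 genes at least 2-fold higher and the 24 at least 2-fold lower in both settings, while Fos, Thbs1 and BC018473 lie along the horizontal axis.

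In the limma test of the difference common to both settings, 231 genes rose and 144 fell. Fkbp5 rose (SE of the mean difference 0.119, adjusted p = 2.58e-05), Tsc22d3 rose by 2.54 (SE 0.145, adjusted p = 2.07e-05), and the receptor gene Nr3c1 itself by 1.16 (SE 0.132, adjusted p = 0.00104). The pro-apoptotic genes Bcl2l11 (Bim), Bbc3 (Puma) and Bmf rose by 1.29, 1.71 and 1.58, with limma adjusted p of 0.000329, 0.000727 and 0.000596, and were higher in both settings. The T-lineage genes Bcl11b and Cd8a fell, with mean differences of -1.21 and -0.99 and limma adjusted p of 0.000402 and 0.000964. The lowest p-values belonged to MGC58382, Nfil3, Ptgr1, Tsc22d3 and Fkbp5 among genes that rose and, among others, to Id3, Bcl11b, Slc16a1, a monocarboxylate transporter gene, and Cd8a among those that fell.

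By list, 11 of 23 canonical glucocorticoid-induced genes rose over all genes tested and 16 adjusted over the list alone. Klf9 (2.34), Ddit4 (1.99) and Per1 (1.07) were among the 11, while Socs1 (-1.03) and Ets2 (-0.77) fell. Of 12 pro-apoptotic genes 3 rose, and 4 did adjusted over the list alone, whereas Pmaip1 (Noxa) was at 1.27 in vivo and -0.48 in vitro. Of 5 anti-apoptotic genes, Bcl2 rose by 1.04 and Bcl2l1 fell by 0.74, while Mcl1 and Bcl2a1a did not pass. Of 18 double-positive thymocyte genes, 8 fell, and 10 did adjusted over the list alone, among them Dntt (-0.79) and Tcf7 (-0.58), while the abundant Satb1 was at -0.09 in vivo and -0.11 in vitro. Of 19 cholesterol synthesis genes 8 fell, and 14 did adjusted over the list alone, with Msmo1 at -1.11 and Sqle, squalene epoxidase, at -1.09. Of 18 T cell receptor signalling genes Lck, Cd5 and Cd3g fell, with 3 rising and 6 falling adjusted over the list alone.

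In other lists, Ncoa2 and Hspa8 rose beside Nr3c1 and Fkbp5 among 11 receptor and chaperone genes, with 4 also adjusted over the list alone. Cd69 and Il7r rose and Ikzf2 fell among 15 mature single-positive genes, Cd69, Pdcd1 and Dusp2 rose and Cd5 fell among 13 activation genes, and Bbc3 rose among 14 p53 targets. Adjusted over the list alone, 4 rose and 1 fell, 4 rose and 3 fell, and 6 rose and 1 fell. Jun rose among 15 immediate-early and heat shock genes (2 rose and 1 fell adjusted over the list alone). It was at 3.17 in vivo and 0.63 in vitro, so a call does not mean equal responses in both settings. Tnfaip3 rose and Cd83 and Ltb fell among 13 NF-kB and cytokine genes (2 and 3), and Usp18 rose and Ifit1 fell among 15 interferon genes (1 and 3). Herpud1 rose by 1.74 and Xbp1 fell among 17 stress response genes, Rrm2 fell among 22 DNA replication genes, and Bub1b rose among 20 mitosis genes, with the same counts adjusted over the list alone. Mgp rose among 10 fibroblast markers, Car2 fell among 4 erythroid markers and Ccr9, also a double-positive gene, fell among 9 dendritic cell markers, with 2, 2 and 2 adjusted over the list alone. In culture Mgp was measured from an ethanol level of 2.75, under 2.97, the lower quartile of all probe set values. For 14 macrophage markers 0 passed over all genes and 1 adjusted over the list alone. For caspases, glycolysis, ribosome biogenesis, thymic epithelium, B cell, endothelial and granulocyte lists 0 passed either way, where the limma test called 375 of all 9882 genes and 1262 had an unadjusted p under 0.05. Without the level filter the limma test called 0 genes, with 1313 at an unadjusted p under 0.05. Without setting as a block it called 0, with 324 at an unadjusted p under 0.05.

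**Figure D3:**
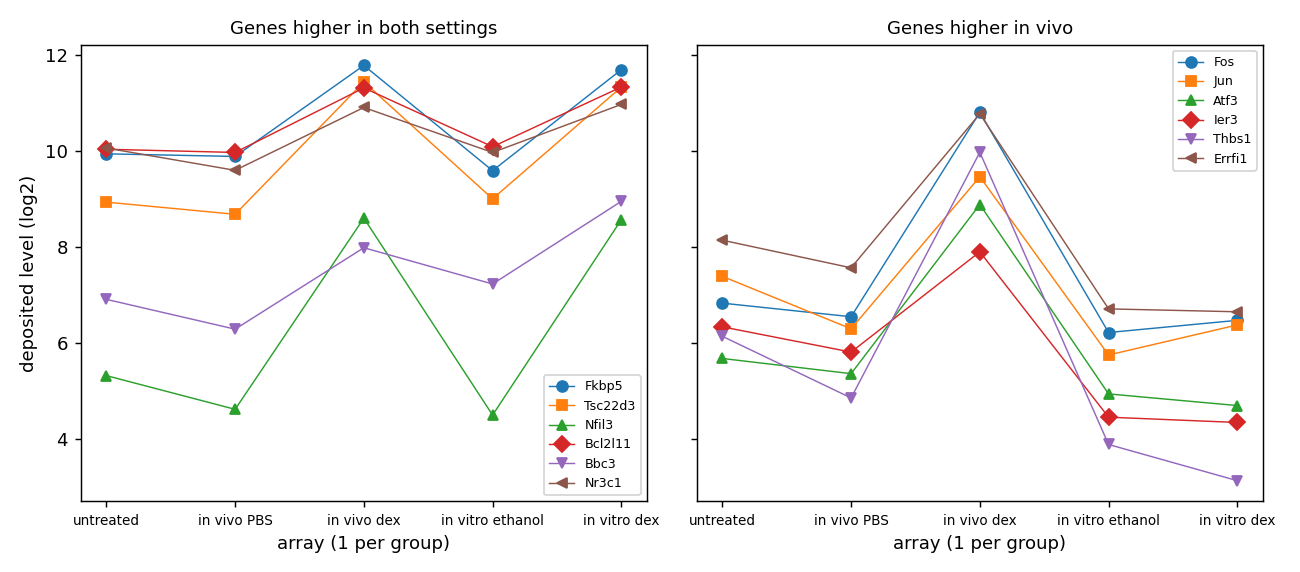
Deposited log2 levels of 12 genes (vertical axis) are shown on the 5 arrays (horizontal axis), with lines only joining the points of a gene. Fkbp5 stood at 11.78 and 11.69 in the dexamethasone arrays against 9.88 and 9.59 in their controls, whereas Fos stood at 10.80 in vivo and 6.47 in vitro with dexamethasone.

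Among the genes whose responses differed most between the 2 settings were the immediate-early genes Fos and Atf3, which stood higher in vivo. The 6 highest in vivo minus in vitro values belonged to BC018473, Thbs1, Fos, Atf3, Ccn1 and Errfi1, which were at 3.21 or more in vivo and at 0.25 or less in vitro. The level of BC018473 did not follow dexamethasone across arrays. It was 9.35 with dexamethasone in vivo and 10.75 in vitro, but 11.02 in ethanol culture, 4.44 untreated and 2.97 with PBS. The 6 lowest belonged to Pdgfrb, Dleu7, Usp18, Plagl1, Nars2 and Nop16, of which Nop16 was lower in vivo (-1.86) and the others were higher in vitro. Those others stood lower in ethanol culture than untreated, with Pdgfrb at -2.45, Plagl1 at -1.96, Nars2 at -1.79 and Dleu7 at -1.12. Against the untreated array, Pdgfrb was at 0 in vivo and 0.42 in vitro, and Plagl1 at 0.52 and 1.12. Nars2 was at 0.96 and 1.75 there, and Dleu7 at 1.13 and 2.99. Usp18, a deubiquitinase of the interferon response, was 2.23-fold higher in vivo and 14.6-fold higher in vitro, from an ethanol level of 5.11 against 8.32 untreated. Against the untreated array Usp18 was at 0.89 in vivo and 0.66 in vitro. The in vivo minus in vitro value was at least 1 for 200 genes and at most -1 for 159, and with 1 array per group it has no test. In ethanol minus untreated, fibroblast, thymic epithelium and macrophage markers had medians of -4.31, -4.28 and -3.22. Thbs1 was at -2.25 there, Ccn1 at -1.59, Errfi1 at -1.43, Atf3 at -0.74 and Fos at -0.61. The settings may therefore differ in their cells as well as in their response, which was not tested.

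Between the PBS and untreated pools, heat shock genes stood highest on the untreated array. Hsph1 was at -3.50, Hspa1b at -3.47 and Hspa8 at -1.17 in PBS minus untreated. The receptor and chaperone list had a median of -0.60, and the immediate-early and heat shock list -0.32. Granulocyte markers were higher by a median of 0.81, with S100a9 at 0.83 and Camp at 0.81. The 8 highest genes were Glp1r (4.26), 1700097N02Rik (3.33), Cirbp (1.91), Glo1 (1.85), Sprr2a (1.76), Sprr2a1 (1.68), Igh-1a (1.49) and Dnah8 (1.38). Among the 8 lowest were Slc15a2 (-5.12), Hsph1, Hspa1b, Myl7 (-2.78), Ifi205 (-2.05), Trim12c (-1.66) and Trim34a (-1.62). In all, 19 genes were at least 2-fold higher and 37 at least 2-fold lower. Mature single-positive genes (0.16) and cholesterol synthesis (0.18) also lay above random lists, and erythroid markers (-0.48), interferon response (-0.26) and stress response genes (-0.21) below. Without the level filter the counts were 30 and 79.

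After 4 h in culture with ethanol, transcripts of thymic epithelium, fibroblasts and macrophages were far lower than in the untreated suspension. Thymic epithelium markers had a median of -4.28, with Krt18 at -7.11, Cxcl12 at -7.02, Prss16 at -6.82 and Ccl25 at -6.77. Stromal fibroblast markers had a median of -4.31, with Col3a1 at -6.56, and macrophage markers -3.22, with Lyz2 at -3.09. Thymocyte lists were not lower, with medians of 0.21 for double-positive and 0.97 for mature single-positive genes, and cholesterol synthesis stood at 0.76. In all, 306 genes were at least 2-fold higher and 797 at least 2-fold lower.

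The 8 lowest genes were Car3 (-7.87), Fabp4 (-7.83), Ccl21a (-7.57), Krt18, Cxcl12, Ubd (-6.97), Tbata (-6.86) and Prss16. The 8 highest were BC018473 (6.58), St6galnac1 (3.65), Cirbp (3.10), Bambi-ps1 (3.08), Tubb2a-ps2 (2.98), Zfyve28 (2.84), Gtf2h4 (2.80) and Carns1 (2.76). Mitosis genes (0.59, with 20 of 20 higher) and T cell receptor signalling genes (0.23) lay above random lists. Below them lay dendritic cell markers (-1.56), interferon response (-1.40), T cell receptor activation response (-1.12), immediate-early and heat shock genes (-1.12), anti-apoptotic Bcl-2 family (-0.97), receptor and chaperones (-0.91), ribosome biogenesis (-0.60), NF-kB and cytokine genes (-0.59), glycolysis (-0.58), p53 targets (-0.40) and canonical glucocorticoid-induced genes (-0.35). B cell (-0.60), endothelial (-0.47), granulocyte (-0.27) and erythroid markers (-0.09) lay within the range of random lists. Of the 1103 genes, 22 had their dimmer array under 2.97, the lower quartile of all probe set values, so their differences run close to the lowest levels of these arrays. All of the 8 lowest genes but Prss16 (4.35) stood under 4.26, the ethanol array's median, in ethanol culture. The sizes of such differences are therefore uncertain for more genes than those 22. Without the level filter the counts were 424 higher and 1411 lower.

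**Figure D4:**
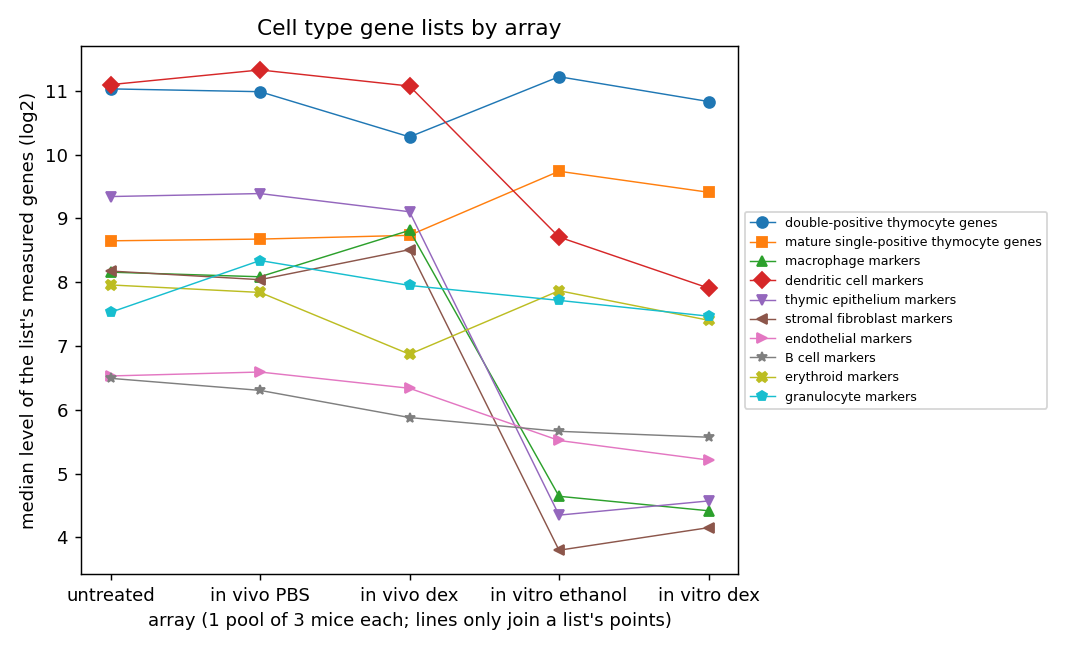
Each point is the median log2 level (vertical axis) of a cell type list's measured genes on 1 of the 5 arrays (horizontal axis), with lines only joining the points of a list. Thymic epithelium markers stood at 9.34 on the untreated array and 4.35 on the ethanol array, and double-positive thymocyte genes at 11.03 and 11.22.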

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

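All tests of explanations in this part were chosen after the result was seen. Arrdc3, an arrestin-domain gene, and Klf15, a Krüppel-like transcription factor, differed by at least 2-fold in opposite directions, with in vivo minus in vitro values of 3.08 and 2.75. Arrdc3 was at 1.70 in vivo and -1.38 in vitro, and another of its 2 probe sets was at -0.81 in vivo. Klf15 was at 1.69 and -1.07, and another of its 2 probe sets was at -0.11 in vivo and 0.18 in vitro. Both were chosen because of these values, and the difference between the settings was not tested.

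Ribosome biogenesis, DNA replication and granulocyte lists lay below random lists in vivo and above them in vitro, with in vivo minus in vitro medians of -0.73, -0.69 and -0.61. These differences were not tested. The granulocyte list had median levels of 7.53 untreated, 8.34 with PBS and 7.95 with dexamethasone in vivo. Its in vivo difference is therefore taken from a PBS array that stood above the untreated one. Of its 7 genes 5 were lower in vivo, while the abundant S100a8 and S100a9 differed by 0.007 and 0.03. Among 702 unnamed probe sets above the level limit, which entered no gene count, 60 differed by at least 2-fold in vivo and 32 in vitro, against 17 between PBS and untreated. Of these, 16 differed the same way in both settings.

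Immediate-early genes were higher with dexamethasone in vivo (Fos 4.26, Atf3 3.52) but not as a group in vitro, where 9 such genes had a median of -0.11. Jun, 1 of them, was at 3.17 in vivo and 0.63 in vitro. The difference between the settings was not tested. More fibroblasts or thymic epithelial cells in the injected pool, as the whole cause, are argued against by those lists, whose higher median in vivo was 0.20. The fibroblast list lay above random lists, with 9 of 10 genes higher and 0 lower, among them Mgp at 1.08. A part from fibroblasts therefore stays open. More macrophages, as the whole cause, are argued against by a list median of 0.43, with the abundant Lyz2 at -0.06 and Ctss at 0.08. Still, 13 of 14 macrophage markers were higher, with Hmox1 at 2.37, Mrc1 at 1.68 and Vcam1 at 1.07, so a part from macrophages stays open. A low PBS array is argued against by the comparison with the untreated array, where the 9 genes had a median of 1.34. Stress while 1 pool was prepared stays open and cannot be told apart from the treatment with a single pool: 4 heat shock genes had a median of 0.26 in vivo, with Hspa1b at 1.03. More adipocytes, whose markers had an in vivo median of 0.75, and a response that culture lacks may also account for the pattern and were not tested.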

How the results depend on the processing

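With 1 array per group no replicate could be left out, and no paired analysis was possible because replicate 1 is the only one in each group, so the limma fit took setting, not replicate, as its block. One alternative, the PBS array in place of the untreated array for the ethanol comparison, was chosen after seeing the data and gave 1040 genes. The deposited log2 and difference tables gave identical counts, since they hold the same values, so these settings test nothing. Counts of at least 2-fold genes stayed within 1.5 times under cyclic loess, centring, the mean of probe sets and without _x_at and _s_at probe sets. Without the level filter in vivo gave 644, PBS against untreated 109 and ethanol culture against untreated 1835. With only the 4941 genes of highest mean level, in vivo gave 154, in vitro 96, both settings 55, PBS 22 and ethanol 287. At 1.5-fold they gave 1368, 802, 383, 414 and 2487, and at 3-fold 129, 66, 34, 14 and 553, as other thresholds must. In vivo more genes were higher than lower at 2-fold (268 and 146), but fewer at 1.5-fold (640 and 728), and the numbers were 246 and 222 with the untreated array as control. With the untreated array as control in vitro gave 1340 and both settings 227, and part of the latter may come from the shared array. The limma test of the common difference depended on its settings: its 375 calls became 126 without the trend, 732 with robust estimation, 121 with the mean of probe sets, 0 without the filter (1313 at an unadjusted p under 0.05) and 0 without setting as a block (324). The prior degrees of freedom differed between these fits, and the cause was otherwise not tested. Of the 375 genes, 126 were also called without the trend, 365 with robust estimation, 290 after loess and 110 with the mean of probe sets. The list medians outside random lists, 28 of 54 where random lists give 2.7, numbered 20 to 29. That 2.7 holds for lists of unrelated genes and is no chance rate for these lists. Without dexamethasone, PBS against untreated had 3 of 27 lists above random lists and 5 below. Single lists kept their side of random lists in 491 of their alternatives, moved in 48 and reversed in 1, interferon response in vitro, whose mean was 0.0786. Named genes kept their side of 2-fold in 1604, moved in 161 and reversed in 15, all with the untreated array as control, where the cause was not tested. In vivo these were Sprr2a 0.38, Sprr2a1 0.0158, Igh-1a 0.36, Hspa1b -2.44 and Myl7 -0.53. In vitro they were Tubb2a-ps2 1.04, Hmgcs1 0.27, Msmo1 0.0560, Ccl21a -6.30, Mt1 -2.23, Cd69 -1.55, Cxcl10 -3.93, Axl -2.46, Col1a1 -1.29 and Mgp -4.08. Signal over background was not assessed with detection calls, and the dimmer array lay under 2.97 for 1 of the 2-fold genes in vivo, 1 in vitro and 22 in ethanol culture against untreated.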

Other observations

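All tests of explanations in this part were chosen after the result was seen. Adipocyte genes, chosen after their values were seen, were also far lower in ethanol culture than in the untreated suspension, with a median of -6.28 over 6 measured genes. Fabp4, a fatty acid binding protein gene, was at -7.83, Lpl, lipoprotein lipase, at -6.31 and Adipoq, the adiponectin gene, at -6.11. In vivo the same 6 genes had a median of 0.75. Peptide transporter gene Slc15a2 stood at 3.73 and 3.81 in both injected pools and at 8.17 or above on the other arrays. Ifi205 was at 7.33 on the PBS array and at 9.37 or above on each of the others.

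Transcripts of thymic epithelium, fibroblasts and macrophages were lower in the cultured suspensions than in the untreated one. Cyclic loess cannot decide on array scaling, because the arrays already had similar medians before it, 4.37 untreated and 4.26 in ethanol culture. After it the members of the 3 lists still had a median of -4.14. Those members lay apart from double-positive thymocyte genes on the same arrays, with a difference of medians of -4.29. A shared factor leaves this difference unchanged, so a loss of RNA alike for all transcripts would not by itself produce it. Whether such a loss also occurred cannot be told from this value, and the 3 lists were chosen because they were low. Fewer tissue-bound cells, from preparation or loss, also stays an open candidate explanation: 89.2% of 37 members were at least 2-fold lower in both cultured arrays, but these lists were chosen because they were low, and endothelial markers were at -0.47, from Plvap at -2.71 to Pecam1 at 0.32. How the cultured suspensions were prepared is not given in the sources used here, and an effect of culture on these cells themselves was not tested.

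Some of the genes that differed between PBS and untreated lie beside each other in the genome (gene order of GRCm38.p6). Of 50 such genes with a position, 13 had another within 10 places, where random sets had a mean of 4.99 and the upper limit of their central 95% was 12. This may reflect genetic differences between pools of outbred mice. Without neighbours of the same symbol root, such as Gprasp1 and Gprasp2, the count was 6 against a random mean of 4.95 and a limit of 11. Gene families may therefore account for the excess in the count too, and the test misses small groups. Those 6 were Ccdc117, Myl7, Glo1, 1700097N02Rik, Dnah8 and Glp1r, which a shared symbol root does not account for. Of them Glo1, 1700097N02Rik, Dnah8 and Glp1r were among the 8 highest genes in PBS minus untreated. A response to injection stays open: the 13 genes had a median of 1.19 in the PBS direction in the dexamethasone-injected pool and 0.67 in ethanol culture, but both differences share the untreated array with the one that chose the genes. In vitro 109 genes had a neighbour against a limit of 98, with or without neighbours of the same root, while in vivo (243 against 245) and ethanol culture (939 against 959) lay under their limits.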
